A study of Homo sapiens with 12 samples.

How the data were processed

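The samples were input RNA and ac4C immunoprecipitates from HK2 cells under hypoxia and reoxygenation with or without NAT10 siRNA, in 4 groups of 3. Per the labels, RNA was enriched for poly-A, fragmented, immunoprecipitated with a commercial ac4C kit and made into directional libraries. The same text says that RNA from an m6A antibody immunoprecipitation was quality controlled, so which antibody gave the immunoprecipitates is not settled by the labels. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, STAR, FastQC and the human build hg19, with no role given for each. In the deposited RNA tables the authors gave raw counts per gene for the 6 input libraries, per the file headers. The same tables held log2 values, namely library-size-scaled counts (CPM) on a log2 scale from edgeR, a log2 fold change and a mean log2 level per gene. The authors also gave an F statistic from edgeR as a score, and a p-value with its false discovery rate. The deposited tables listed only genes with a fold change of at least 2.00 and a p-value of at most 0.05, per the file headers. In the deposited ac4C tables the authors gave each site's position, its fold change as a ratio of the larger over the smaller group, a p-value and a score equal to the -log10 p-value. The largest p-value the authors listed for a site was 9.87e-06. How the input and the replicates entered the site values is not stated, and site values were used as the authors gave them. The share of listed RNA genes with a mouse gene database cross-reference was 96.2%, and all identifiers were of mouse, which the build named in the notes is not. Of the per-sample columns, 0 were left unused.

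The effective library size of each input library was recovered from the relation between its counts and its log2 values, with a misfit of at most 3.91e-14. Tested on simulated data, this recovery erred by at most 3.41e-06 percent. Sizes were 13231841, 14711090 and 9844817 counts in H/R and 6522414, 7808859 and 8073088 counts with NAT10 siRNA. The listed genes held 1.42 to 2.23 percent of each library. The number of genes tested by the authors, 15642, followed from the ratio of false discovery rate to p-value at the smallest p. Of the genes in that test at least 2458 had a false discovery rate of at most 0.05, of which 590 were listed, the rest lying outside the fold limit. The floor was 3 counts over the summed library size of a group, and floors cover counting error only.

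Counts were fitted with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the recovered library sizes, with no covariate. The p-values were adjusted by Benjamini-Hochberg over 15642 genes, the unlisted genes being counted as not passing, at a threshold of 0.05. At least 2458 genes passed the authors' own false discovery rate at that threshold, most of them unlisted. Listed genes thus took ranks that were too low, which by itself makes their adjusted p-values too large. A call missed or lost near the threshold is therefore not evidence of no change. The design fixed the test but not the number to adjust over, which was chosen when the tables were seen to be filtered and before the refit. The refit was on genes that the authors had chosen on these samples, so it is not independent evidence. The prior degrees of freedom of the fit were 246 against 4 residual ones, so each gene's spread was drawn almost wholly to the trend of these chosen genes. They were 12.2 among genes with a mean of at least 1 CPM and 8.80 without NAT10 siRNA replicate 1. Without H/R replicate 1, 2 or 3, and without H/R libraries 1 and 2, they were infinite, so no gene's own spread entered. Very small p-values should therefore be read as past the threshold and not by their size. The refit had the authors' sign in all 1090 genes, with a median absolute difference of 0.00113 in log2 fold change. Tested on simulated data with 200 changed genes, the test called 23 of 100 genes with a log2 change of 1, 66 of 100 with a change of 2, and 0.787 percent of unchanged genes. The simulated calls were adjusted over the 1090 simulated genes and not over 15642, so these rates do not describe the refit as run. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples. Replicates were checked for duplication by the mean chi-square per listed gene between libraries, which was 10.9 to 30.1 among H/R and 3.28 to 4.11 among NAT10 siRNA libraries. Deviations of same-numbered libraries correlated by at most 0.0140, so the numbers were not treated as pairs, and a replicate block was tried as an alternative.

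The 36 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took NAT10, the genes in the series title, up to 4 members per list with the smallest authors' p-value, and the 10 genes per direction with the largest log2 fold change among those with a mean of at least 1 CPM in the higher group. It also took the 5 sites per direction with the largest fold, and the 10 genes lower and 5 genes higher in both tables with the largest summed change. Lists were tested for direction with Fisher's exact test, two-sided, against all listed genes, where at least 5 members were listed, and adjusted over the lists tested. On simulated lists the test called the planted list of 12 genes and 0 of 20 random lists. Lists had no listed RNA member in 11 cases, among them cytosolic ribosomal proteins and RNA modification enzymes. RNA and site changes were compared with Fisher's exact test and with Pearson and Spearman correlations across genes, using the median over a gene's sites and 100000 permutations, two-sided. A gene symbol shared between identifiers led 4 entries to be left out of that join. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used, and DESeq2 1.42.0 served as an alternative.

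The alternatives changed the fold and p thresholds, the filter on low levels, the normalization, the replicates, the block, the unit in which sites were counted and the choice of site per gene. Base composition and transcript region of sites were not analysed here, as no genome or annotation of the organism of the identifiers was used. Sites were not refitted without replicates, as their values are per group. Neuronal and glial markers, numbering 70, were listed by hand after the largest folds had been seen.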

Results

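The series set out to compare RNA levels and N4-acetylcytidine (ac4C) sites in HK2 cells, a human proximal tubule line, after hypoxia and reoxygenation (H/R) with and without siRNA against NAT10. NAT10 is the enzyme that writes ac4C on RNA. The labels describe 12 samples in 4 groups of 3, with input RNA and ac4C immunoprecipitate for each condition. The deposited tables listed genes and sites that the authors had already called as changed, so a gene missing from them was not shown to be unchanged. Effective library sizes of the input were 9844817 to 14711090 counts in the H/R libraries (mean 12595916 ± 2494685, SD, n = 3) and 6522414 to 8073088 counts with NAT10 siRNA (mean 7468120 ± 829593, SD, n = 3). A summed count of 0 in a group allowed up to 0.0794 CPM, the count scaled to the effective library size, in H/R and 0.134 CPM with NAT10 siRNA. All 1090 listed RNA genes carried mouse Ensembl identifiers, although the labels name human cells, and symbols are printed below as the files give them.

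NAT10 itself was in 0 of the listed RNA genes and carried 0 of the listed sites, so its silencing could not be read from these tables. The series title names the chemokine genes CCL2 and CXCL1, and both were listed lower with NAT10 siRNA. Cxcl1 (ENSMUSG00000029380), which encodes a neutrophil-attracting chemokine, fell from 683 ± 182 CPM to 122 ± 2.28 CPM (SD, n = 3 per group). Its log2 fold change was -2.49 with a standard error of 0.16 (edgeR adjusted p = 7.56e-34, against the authors' own false discovery rate of 0.000114 for Cxcl1). Ccl2 (ENSMUSG00000035385), which encodes a monocyte-attracting chemokine, fell from 2.97 ± 3.38 CPM to 0.165 ± 0.286 CPM, a log2 fold change of -4.00 with a standard error of 0.91 (edgeR adjusted p = 0.00110). The Ccl2 fold was not stable, as its log2 value ran from -7.97 to -2.54 over the leave-outs of 1 library and was -1.17 without H/R libraries 1 and 2. Its counts in the H/R libraries were 90, 25 and 4, against 0, 0 and 4 with NAT10 siRNA, so the groups overlapped. The Ccl2 call was lost without H/R replicate 1 (adjusted p = 1) and without NAT10 siRNA replicate 1 (adjusted p = 0.580). Over all alternatives its adjusted p ran from 2.04e-06 to 1, whereas that of Cxcl1 stayed past the threshold in each.

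Signalling genes of inflammation were mostly lower with NAT10 siRNA. Of the listed chemokines, 6 fell and 1, Cxcl10, rose, from 1.43 ± 0.871 to 4.99 ± 2.69 CPM, a call kept in 1 of 6 leave-outs of a library. Cxcl2 fell from 89.9 ± 26.8 to 17.8 ± 4.37 CPM, with a log2 fold change of -2.34. All 6 listed cytokines fell. Csf3, the granulocyte colony-stimulating factor gene, fell from 114 ± 15.2 to 11.1 ± 1.55 CPM (log2 fold change -3.35 ± 0.23 SE, edgeR adjusted p = 6.62e-32). Csf2, the granulocyte-macrophage colony-stimulating factor gene, fell from 17.5 ± 6.73 to 1.65 ± 0.845 CPM, and Il1a from 355 ± 48.4 to 162 ± 5.79 CPM. Tnf had a mean of 1.43 ± 0.884 CPM in H/R and 0 counts in every NAT10 siRNA library, at least 11.3-fold lower at the floor of 3 counts over the group. The Tnf call was lost without H/R replicate 2 (adjusted p = 0.574) and without each NAT10 siRNA library, over leave-outs from 0.000366 to 0.574. Genes of the NF-kB pathway and its targets included 10 that fell, among them Tnfaip2 (894 ± 73.5 to 328 ± 10.8 CPM), the inhibitor gene Nfkbie (67.0 ± 12.1 to 16.1 ± 2.69 CPM), Ikbke and Traf1. The 1 member on the other side was Ptgs2, the inducible prostaglandin synthase gene, named after its values were seen, which rose from 779 ± 127 to 1966 ± 164 CPM. Counts adjusted over the list alone equalled those adjusted over all tested genes in these 3 lists, at 6 lower and 1 higher, 6 and 0, and 10 and 1. Fisher's exact tests gave none of these 3 lists a direction apart from that of all listed genes (adjusted p = 0.793 for chemokines and 1 for cytokines and NF-kB). As 88.3% of the listed genes were lower, even a list of this size wholly lower, as the cytokines were, could not pass. These tests thus could not decide on a lower direction of a list's own. With scale factors taken from the listed genes alone, 3 chemokines and 2 cytokines were still called lower, NF-kB genes were called lower in 0 cases, and Il1a flipped direction. These factors centre the listed genes, most of them lower, and so raise every log2 fold change. Small falls thus turn positive by construction, here and below, which is not evidence that those genes were unchanged. The lists were fixed before the data were examined, but the authors chose the listed genes on these samples, so a count of members is not independent evidence of direction.

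**Figure D1:**
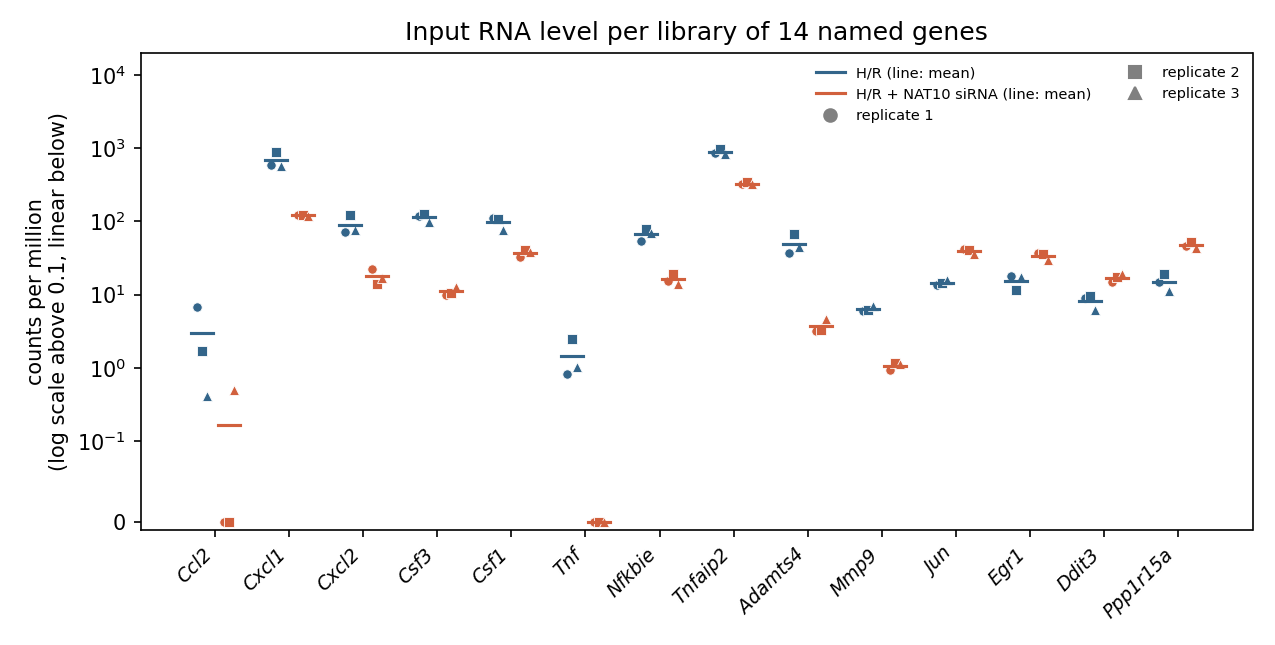
Level of 14 named genes in each input library, in CPM on a scale that is logarithmic above 0.1 and linear below, with symbols for replicates and a line at the group mean (n = 3). Cxcl1 fell from a mean of 683 to 122 CPM, while the H/R libraries of Ccl2 ran from 6.80 down to 0.406 CPM and overlapped the NAT10 siRNA library at 0.495 CPM.

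Matrix protease and histone genes were lower as well. All 8 listed genes of the matrix protease list were on the lower side, of which 6 passed over all tested genes and 8 when adjusted over the list alone. With scale factors from the listed genes alone 1 of the 6 calls was left. Fisher's exact tests gave the protease, histone, interferon, p53 and extracellular matrix lists no direction apart from that of all listed genes (adjusted p = 0.793 for each). The protease and histone lists, at 8 and 10 genes, were wholly lower and still had unadjusted p of 0.607 and 0.617 in that test. A lower direction of a list's own could thus not have been shown at these sizes. Adamts4, an aggrecan-cleaving protease gene, fell from 49.4 ± 15.7 to 3.71 ± 0.757 CPM (log2 fold change -3.72 ± 0.29 SE, edgeR adjusted p = 3.02e-25). Mmp9, the gelatinase B gene, fell from 6.39 ± 0.536 to 1.06 ± 0.125 CPM. All 10 listed replication-dependent histone genes were on the lower side, of which 9 passed over all tested genes and 10 when adjusted over the list alone. Among them were Hist1h1b (149 ± 13.3 to 71.6 ± 1.27 CPM) and Hist1h1c (153 ± 25.1 to 67.1 ± 8.15 CPM). The direction of all 10 histone genes flipped when scale factors were taken from the listed genes alone, which turn falls of this size positive by construction. Of the interferon-stimulated genes 6 were listed lower and 2 higher. The 4 lower ones that passed were Samd9l, Irf1, Parp14 and Xaf1, of which Samd9l and Irf1 flipped in the same way. The 1 higher one that passed, Ifit1, rose from 2.22 ± 1.94 to 17.6 ± 2.69 CPM. The Ifit1 call was lost without NAT10 siRNA replicate 1 (adjusted p = 0.171) and with DESeq2 (0.821), over a range that began at 3.18e-28, with 0.169 as the authors' own false discovery rate for Ifit1, and those of Parp14 and Xaf1 were lost without the same replicate (0.0594 and 0.0665). Of the p53 and apoptosis list 4 genes fell, led by Bcl2l11, which encodes the death-promoting protein BIM (114 ± 20.9 to 30.8 ± 5.62 CPM). Vcam1, an adhesion molecule gene, and Itgb6, an integrin gene, were the 2 listed kidney injury markers, and both fell, Vcam1 from 1164 ± 359 to 395 ± 13.1 CPM, while Itgb6 flipped with factors from the listed genes. In the list of extracellular matrix genes only Itgb6 passed, out of 4 listed lower and 1 listed higher.

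Stress and immediate early genes stood on the higher side. Of 6 listed immediate early genes 5 were listed higher and 1 lower, a direction apart from that of the other listed genes (Fisher's exact test, two-sided, p = 0.000110, adjusted p = 0.000988 over 9 lists). That test counts genes as independent, which genes that change together are not, so its p does not measure spread between samples. Of the 6 genes 4 passed, both over all tested genes and adjusted over the list alone. Jun rose from 14.6 ± 1.16 to 39.5 ± 2.90 CPM (log2 fold change 1.43 ± 0.26 SE, edgeR adjusted p = 7.65e-06), and Dusp8, Egr1 and Atf3 rose too. The calls of Dusp8, Egr1 and Atf3 were each lost without NAT10 siRNA replicate 1, with adjusted p of 0.120, 0.162 and 0.428, and that of Egr1 also without H/R replicate 2 (0.0566). Over all alternatives the adjusted p of Dusp8, Egr1 and Atf3 began at 3.77e-19, 5.23e-19 and 6.64e-19 and ended at the values without NAT10 siRNA replicate 1. Fos and Fosb, named after their values were seen, had log2 fold changes of 1.11 and -1.05 and did not pass (adjusted p = 0.389 and 0.709). With the 4 genes that passed alone, the list fell under the minimum of 5 members and had no test. All 4 listed genes of the unfolded protein and integrated stress response rose, among them Atf3, which is also in the immediate early list. Ppp1r15a, which encodes the GADD34 phosphatase subunit, rose from 14.9 ± 4.02 to 47.7 ± 5.03 CPM (log2 fold change 1.67, edgeR adjusted p = 3.31e-08). Ddit3, Atf3 and Chac1 had log2 fold changes of 1.03, 1.01 and 1.12, and kept their calls in 1, 4 and 2 of the 6 leave-outs, with a highest adjusted p of 0.387, 0.428 and 0.737, while the log2 fold change of Chac1 ran from 0.88 to 1.70. Hmox1, the heme oxygenase gene induced by oxidative stress, rose from 57.3 ± 7.97 to 122 ± 10.9 CPM. Adm, a gene induced by hypoxia, rose to 1.60 ± 0.480 CPM from 0.0591 ± 0.0528 CPM, a call kept in 2 of the 6 leave-outs (highest adjusted p = 0.478).

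**Figure D2:**
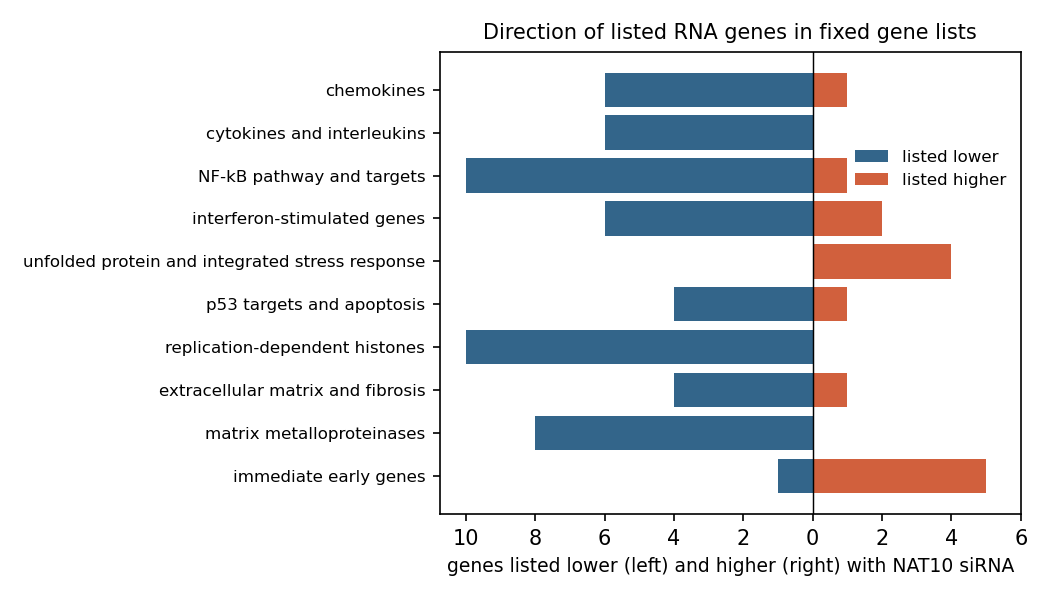
Number of listed RNA genes per fixed gene list, lower (left) and higher (right) with NAT10 siRNA, for lists with at least 4 listed genes. Immediate early genes were listed 5 higher and 1 lower against 127 higher and 963 lower over all listed genes. All 10 histone genes flipped direction when scale factors came from the listed genes alone, which raise every log2 fold change by construction.

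Over all genes, the authors listed 127 as higher and 963 as lower with NAT10 siRNA. A refit of the deposited counts with edgeR, adjusted over the 15642 genes the authors tested, called 49 higher and 373 lower at an adjusted p of 0.05. Every unlisted gene was ranked after the listed ones, which by itself makes the adjusted p-values too large. The authors' own false discovery rate also passed 44 of these 49 and 357 of these 373. The size of the refit's p-values depended on which genes and libraries entered the fit. The prior degrees of freedom for the spread were 246 over the listed genes and 12.2 over those with a mean of at least 1 CPM. They were 8.80 without NAT10 siRNA replicate 1 and infinite without H/R replicate 1, 2 or 3. Calls kept without an H/R library thus did not weigh a gene's own spread. Scale factors taken from the listed genes alone moved the median log2 fold change by 1.38 and gave 80 higher and 23 lower, so that 77.7% of the calls were higher in place of 11.6%. Without NAT10 siRNA replicate 1 the counts were 18 and 97, and the lower count was 238 without H/R replicate 2 and 247 without NAT10 siRNA replicate 3. Of 64 named genes that passed, 24 lower and 5 higher ones kept the call without each library in turn. The higher ones were Ppp1r15a, Hmox1, Jun, Csrnp1 and Zbtb40. Of the 24 lower ones, 6 also kept it with scale factors from the listed genes, namely Cxcl1, Cxcl2, Csf3, Csf2, Adamts4 and Tns4. These factors raise every log2 fold change, so they favour large falls and put higher genes to no test.

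The largest lower folds belonged to low-abundance genes, several of them known from neurons. Snap25, a synaptic vesicle fusion gene, had 3.10, 3.33 and 0 CPM in the H/R libraries and 0 counts with NAT10 siRNA, at least 17.8-fold lower at the floor over the group. Snhg11, Ttr, Dnm1, Tmod2 and Slc24a2 were likewise at 0 in every NAT10 siRNA library and at least 20.6-fold, 18.6-fold, 14.2-fold, 12.8-fold and 11.5-fold lower. These bounds are against the pooled H/R libraries and do not hold for H/R library 3 alone, where these genes had 0, 1, 3, 8 and 0 counts. All 6 calls were lost without NAT10 siRNA replicate 1, where the adjusted p ran from 0.149 for Tmod2 to 0.554 for Slc24a2. Of a list of 70 neuronal and glial markers drawn up after these genes were seen, 29 were listed lower and 0 higher. Their summed level was 85.5, 104 and 30.7 CPM in H/R libraries 1, 2 and 3, and 10.1, 3.97 and 10.5 CPM in the NAT10 siRNA libraries. Few markers carried the sum in H/R library 3, where Dlgap1 gave 17.4 CPM and 18 of the 29 had 0 counts, against 21, 21 and 19 in the NAT10 siRNA libraries. The pattern was not limited to the genes on this list. Of all lower genes 108 had at most 0.1 of the mean level of H/R libraries 1 and 2 in library 3, and 87 of these were outside the marker list. Among the 87 were Ccl2 (90, 25 and 4 counts) and Slc24a2 (35, 23 and 0 counts). The list was drawn up by hand, so genes outside it can be neuronal too, and how many are was not counted. The same low level in library 1 or 2 against the other H/R libraries was seen in 33 and 16 genes. Of the 108 genes 12 passed the adjusted p. The lower count was 361 without the marker genes and 241 without H/R libraries 1 and 2, with 43 higher, and 225 and 40 of these genes were shared with the calls on all libraries. Without those libraries 1 H/R library was left, whose spread was taken to be that of the NAT10 siRNA libraries. Among the largest higher folds, Csrnp1 rose from 3.28 ± 2.21 to 19.9 ± 2.24 CPM, and Zbp1, a nucleic acid sensor gene, from 0.227 ± 0.392 to 2.39 ± 1.19 CPM. The Zbp1 call was kept in 3 of the 6 leave-outs (highest adjusted p = 0.952).

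**Figure D3:**
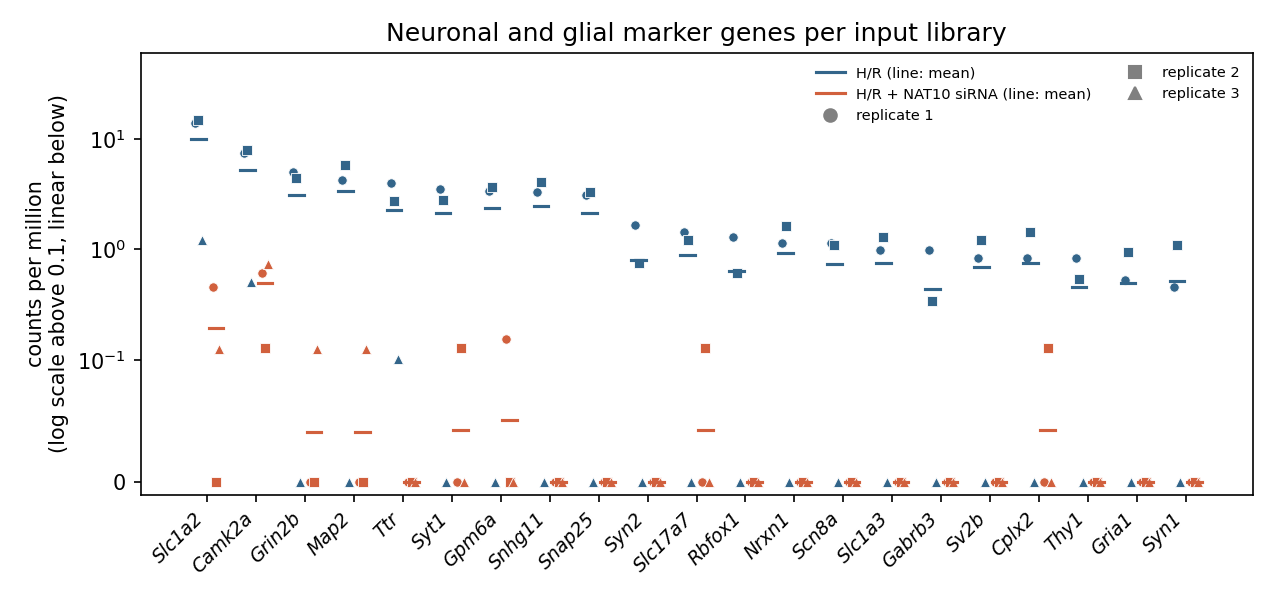
Level of 21 neuronal and glial marker genes in each input library, in CPM on a scale that is logarithmic above 0.1 and linear below, with symbols for replicates and a line at the group mean (n = 3). The summed level was 60.2 and 61.7 CPM in H/R libraries 1 and 2 and 1.83 CPM in H/R library 3, a group picked for a low level in that library.

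The ac4C tables listed 213 sites as higher, on 153 genes, and 636 as lower, on 400 genes, so that 74.9% of the listed sites were lower with NAT10 siRNA. Sites are called ac4C as in the labels, although the protocol text also names an m6A antibody. The median fold was 3.27 for lower and 2.65 for higher sites, by the authors' own values, and no value per sample was used for sites, so no spread between replicates can be given. The Ccl2 site (chromosome 11, positions 82035571 to 82035737, build not stated in the file) was 3.80-fold lower. The Cxcl1 site (chromosome 5, positions 90891241 to 90891380) was 6.25-fold lower. In the fixed lists, 11 NF-kB genes had lower sites and 1 a higher site, 9 histone genes and 8 mitotic genes had lower sites only, and chemokines and cytokines each had 6 genes with lower and 1 with higher sites. The genes with higher sites were Ccl5 and Il11, and in the NF-kB list Ptgs2. The mitotic genes included Top2a, Aspm and Cenpf, with folds of 2.03, 2.61 and 2.20. On the other side, 4 immediate early genes (Jun, Egr1, Klf6 and Dusp8) had higher sites and 1, Egr2, a lower site (Fisher's exact test, two-sided, p = 0.0220, adjusted p = 0.132 over 6 lists). The listed hypoxia and glycolysis genes Ndrg1, Pfkfb4 and Pgam1 had higher sites, with folds of 6.71, 3.92 and 2.78. Of the 6 lists with enough genes, 0 passed after adjustment. The histone and mitotic lists had lower sites only and still had unadjusted p of 0.0692 and 0.114 (Fisher's exact test, two-sided). These 2 lists thus could not have passed on the lower side.

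Some genes carried many sites. Bahcc1 had 13 lower sites, Ksr1 had 11 and Adamts4 had 8 with a median fold of 12.8, while Dusp8 had 6 higher sites with a median fold of 3.15. Of the genes with lower sites 29.5% had more than 1, against 23.5% of those with higher sites (Fisher's exact test, two-sided, p = 0.170). Among sites with an absolute log2 fold change of at least 2 the shares were 22.5% and 2.5% (Fisher's exact test, two-sided, p = 0.00239). The largest lower folds were 146 in Zc3h7a, 122 in the testis histone gene Hist1h1t and 120 in D030025P21Rik, and the largest higher folds were 106 in Cln8 and 76.0 in Isl2. The Zc3h7a site was 3 bases long, and the 2-base Adamts4 site had a fold of 100.4. The only gene with sites in both directions was Sphk2, a sphingosine kinase gene.

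Transcript and ac4C changes were compared over the 208 genes found in both kinds of table. Of these, 178 were lower in both and 28 higher in both, so that 99.0% shared a direction (Fisher's exact test, two-sided, p = 1.11e-32). How the input entered the site folds is not stated. If they were not corrected for it, a shared direction would follow from the transcript change alone, so the 2 changes cannot be taken as separate. The 2 exceptions were Senp8 and Plekhb1, which had lower RNA and a higher site, named after their values were seen. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.723 and a Spearman rho of 0.656 (permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 1.11e-05 over 10 correlations). Since the genes formed separate groups by direction, r was also taken within them and was 0.467 among genes lower in both and 0.507 among genes higher in both (permutation p = 1e-05 and 0.0304). Csf3 had log2 fold changes of -3.35 in RNA and -3.22 at its sites, Cxcl1 of -2.49 and -2.64, Adamts4 of -3.72 and -3.67, Jun of 1.43 and 1.65, and Ppp1r15a of 1.67 and 1.63. Other genes differed more, with the larger change in RNA for Ccl2 (-4.00 against -1.93) and Tnf (-6.86 against -3.83). Among genes with the largest summed change, Zkscan7 and Ift140 had site values of -5.96 and -5.87 against -1.52 and -1.25 in RNA, and Zbtb40 had 4.99 against 1.55. The direction of Ift140 in RNA flipped with scale factors from the listed genes alone.

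**Figure D4:**
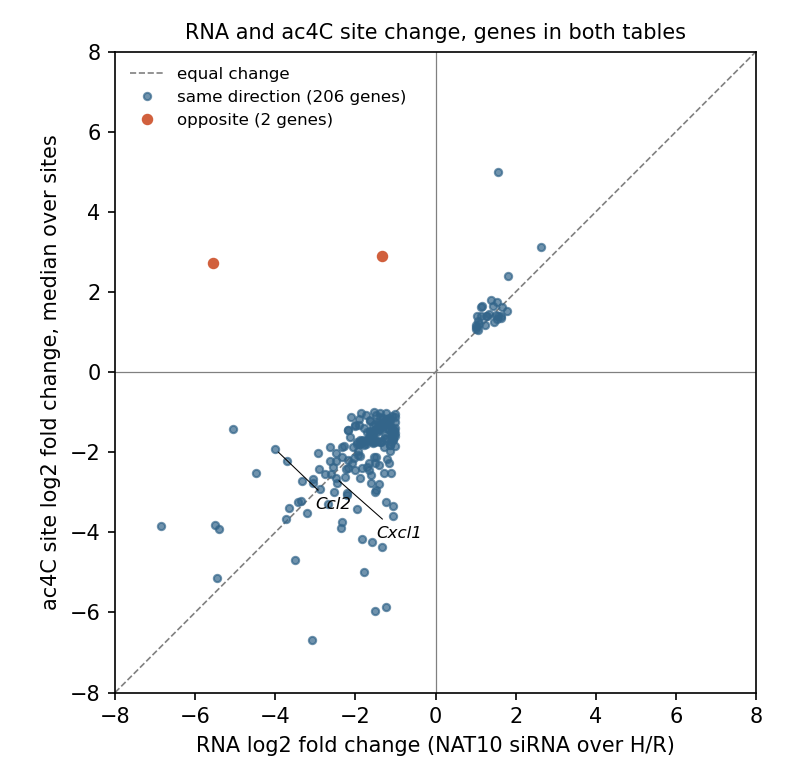
RNA log2 fold change (horizontal) against the median ac4C site log2 fold change (vertical) for the 208 genes in both tables, by the authors' values, with a dashed line at equal change. Points lie in the lower left for 178 genes and in the upper right for 28, and 2 genes have lower RNA with a higher site. Whether site values were corrected for the transcript level in the input is not stated.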

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

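The refit called 49 genes higher and 373 lower, and the alternatives on the number of tests, the libraries with neuronal transcripts, the source of the call, the marker genes and the depth, and the lists of called genes alone, were chosen after seeing the data. An absolute log2 fold change of at least 2 gave 6 higher and 130 lower, and an adjusted p of at most 0.001 gave 26 and 177, each keeping fewer genes by construction. A mean of at least 1 CPM gave 32 and 240. Genes that stayed in lost calls too, and the prior degrees of freedom of the fit fell from 246 to 12.2, but how much each step took was not tested. TMM factors from the listed genes gave 80 and 23, and DESeq2 size factors from them 80 and 24. Both centre the listed genes, of which 88.3% were lower, and so move the zero point by construction. Adjusting over the listed genes alone gave 92 and 809, as fewer tests were counted. Thinning every library to the smallest size left 27 and 162, fewer counts being the cause by construction. Without H/R libraries 1 and 2 the counts were 43 and 241, with 1 H/R library left, whose spread was taken to be that of the NAT10 siRNA libraries. Leaving out each library in turn gave 18 to 52 higher and 97 to 416 lower, the lowest of each without NAT10 siRNA replicate 1. There the prior degrees of freedom were 8.80, so losses may owe to the fit as well as to the library. Without H/R replicate 1, 2 or 3 they were infinite, so counts there, up to 416 lower, may owe to the fit too. The counts stayed within 1.5 times with the replicate number as a block (47 and 331), with DESeq2 on the recovered sizes (39 and 289), at an adjusted p of at most 0.01 (38 and 270) and by the authors' own false discovery rate (59 and 531). Same-numbered libraries correlated by 0.0140, 0.0089 and 0.0093, each more than with the other numbers but under 0.1, so the block is not known to pair cultures.

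Sites with an absolute log2 fold change of at least 2 numbered 41 higher and 219 lower, and genes in place of sites numbered 400 lower, as a gene can hold several sites. Merging overlapping sites changed neither count, and the p limits for sites removed no site, so they tested nothing. The 1 list with its own direction in RNA became 0 at an absolute log2 fold change of at least 2, with called genes alone, and with genes called without H/R libraries 1 and 2, each time because under 5 immediate early genes were left. It stayed at 1 with a mean of at least 1 CPM. The difference in the share of genes with more than 1 site rose from 5.97 to 20 percentage points at an absolute log2 fold change of at least 2 and passed its test, and the cause was not tested. The shared direction of RNA and sites and their correlation kept sign and side of the threshold in every alternative run.

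Under the TMM and the DESeq2 factors from the listed genes, log2 fold changes of named lower genes turned positive. They were 0.26 and 0.25 for Il1a, 0.34 and 0.33 for Samd9l, 0.17 and 0.16 for Irf1, 0.41 and 0.40 for Casp9, 0.33 and 0.32 for Cdca2, 0.13 and 0.12 for Dlgap5, 0.38 and 0.36 for Gins1, and 0.33 and 0.31 for Ccne1. They were 0.16 and 0.15 for Hist1h1d, 0.34 and 0.32 for Hist1h1b, 0.21 and 0.20 for Hist1h1c, 0.072 and 0.059 for Hist1h4f, 0.046 and 0.036 for Itgb6, 0.33 and 0.31 for Cd14, 0.25 and 0.24 for Bbs1, and 0.14 and 0.12 for Ift140. Tgfb1 turned to 0.001 with TMM factors only. The zero point of these scalings is the cause by construction. Splitting the 6 libraries in all 10 ways gave 1 split with as many genes lower and 1 with as many higher, the real one, with 0 genes as the highest of the others in each direction. With 10 splits the share cannot come under 0.05. The authors had also chosen these genes for differing across the real split, so the lack of calls in the others follows from that choice and decides nothing. The pseudocount alternatives were not run, as counts were given, nor were site alternatives without replicates, base composition and transcript region. In simulated data at this depth, adjusted over the 1090 simulated genes alone, 23 of 100 genes with a log2 change of 1 were called. Changes of that size were thus often missed in the simulation, whose rates do not carry over to the refit adjusted over 15642 genes.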

Other observations

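The tests of explanations in this part were chosen after the results they bear on had been seen, while the gene lists, the named genes and the leave-outs were planned. Several smaller gene groups were listed as well. Both listed mitotic genes fell, Cdca2 from 91.4 ± 15.5 to 43.6 ± 2.81 CPM (call lost without NAT10 siRNA replicate 1, adjusted p = 0.0767, within 8.16e-10 to 1) and Dlgap5 (call kept in 2 of 6 leave-outs), and both listed cilium and centrosome genes, Cep72 and Bbs1, fell (calls kept in 4 and 1 of 6 leave-outs), although Cdca2, Dlgap5 and Bbs1 flipped direction with scale factors from the listed genes alone. The replication genes Gins1 and Ccne1 had log2 fold changes of -1.01 and -1.07 and did not pass. The epithelial sodium channel gene Scnn1a fell from 4.70 ± 0.690 to 0.880 ± 0.457 CPM, and its call was lost without NAT10 siRNA replicate 1 (adjusted p = 0.173) and replicate 3 (0.0677), within 0.000337 to 1 over all alternatives. The inflammatory caspase gene Casp4 fell from 5.69 ± 3.95 to 1.18 ± 0.893 CPM, a call lost without H/R replicate 1 (adjusted p = 0.309) and NAT10 siRNA replicate 1 (0.562), within 0.000271 to 1. Cd14, a lipopolysaccharide co-receptor gene, fell from 69.7 ± 24.3 to 33.2 ± 3.48 CPM, lost its call without NAT10 siRNA replicate 1 (adjusted p = 0.150, within 1.19e-05 to 1) and also flipped with those factors. The listed members of other lists had few counts and did not pass, namely Tap1, Nlrp3, Cldn3, Slc17a3, Scnn1g, Thy1, Fap and Cd48 on the lower side and Tal1 and Myl9 on the higher side. Tns4, a tensin gene, fell from 12.4 ± 6.72 to 1.08 ± 0.725 CPM, and Calcb, a calcitonin-related peptide gene, from 4.60 ± 3.13 to 0.358 ± 0.387 CPM, a call that Calcb lost without NAT10 siRNA replicate 1 (adjusted p = 0.226, within 3.85e-07 to 1). Among further list members, sites were higher in Sars, a seryl-tRNA synthetase gene (8.91-fold), and Col7a1 (6.33-fold), and lower in Cd40 (77.4-fold) and Ubtf (2.51-fold).

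The identifiers of every listed RNA gene were of mouse under labels that name a human line and build. Human coordinates under mouse names were tested by asking whether sites lay on the human gene's chromosome. They did in 10.15% of 453 genes, against a mean of 5.51% with chromosomes shuffled, which argues against human coordinates. Whether mouse material was sequenced, or human reads were counted against mouse genes, was not tested, and the organism of the libraries stays open.

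Site folds followed transcript folds. A candidate explanation is that site folds were not corrected for the transcript level in the input, and the median of site minus RNA log2 fold change over the 208 shared genes was -0.01828 (bootstrap interval -0.081 to 0.040), with a median absolute difference of 0.307 against 0.570 with genes shuffled within direction. Among genes lower in both the values were 0.360 and 0.636 with a slope of 0.50, and among genes higher in both 0.207 and 0.285 (permutation p = 0.0661). The measure thus missed its threshold among the 28 higher genes, and both tables hold called genes only, which limits the values each can take, so this stays open. Less ac4C per transcript after NAT10 silencing stays open too. Among 342 genes with sites and no listed RNA change, 64.33% had lower sites (95% exact interval 59.0 to 69.4%), but an RNA change under the listing limit would give the same. This explanation also predicted site values well under RNA values in the median. The median difference of -0.01828 over the shared genes did not reach the limit set for that, though called genes alone limit this measure as well.

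Neuronal transcripts were high in H/R input libraries 1 and 2, as were 87 lower genes outside the marker list. Ccl2 was among these 87, and others of them can be neuronal too. The tests below do not cover the 87. Lower depth of the other 4 libraries is argued against, since 27 of the 29 lower markers had fewer counts there than counting at that depth allows (binomial, adjusted over all 15642 tested genes, as markers were listed for being lower), and 11 did in H/R library 3 alone. A candidate source is RNA of another source in those libraries, which would hold the markers in 1 ratio, and the mean chi-square per gene between libraries 1 and 2 was 1.643, under the 2.5th percentile of 3.05 for other lower genes of like count though above the upper bound of 1.61 from simulations with 1 ratio. The 21 markers were picked for a low level in H/R library 3 only after all 29 lower markers had given 4.19, which was not under their percentile of 3.95, so the test leaves this open, and Thy1 is also in the fibroblast list. Loss of these transcripts on NAT10 silencing also stays open, as the summed level of all 29 markers in H/R library 3, the only other unsilenced one, was 0.3231 of that in libraries 1 and 2, but Dlgap1 held 171 of its 302 counts and 18 markers were at 0 there, and a single library does not decide it.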
